A study of Mus musculus with 18 samples.

How the data were processed

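Gene expression was measured by 1-colour Cy3 hybridisation to NimbleGen mouse oligonucleotide arrays, 1 array for each of 18 RNA samples. Per the labels, naive CD4 T cells (sorted by surface markers, among them TCR beta and CD4, and negative for CD44) came from spleen and lymph nodes of Smad3-deficient mice (KO) or their wild-type littermates (WT), each replicate from at least 2 mice. The cells were cultured for 6 h in serum-free medium, in medium with TGF-beta at 2.5 ng/ml, or in medium with the same TGF-beta, plate-bound anti-CD3e at 10 µg/ml and soluble anti-CD28 at 1 µg/ml. The last condition is called TCR stimulation below, and since it also held TGF-beta it was compared with TGF-beta alone. RNA was reverse transcribed from oligo-dT primers and labelled with random primers.

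The deposited values are linear Cy3 intensities per probe, which the authors background-corrected and normalized with RMA, whose version is not given. The sorted intensities of the 18 arrays were the same to within 0.0651 on the log2 scale at every rank, with a median range of 0.000514, so the arrays had been quantile normalized as 1 set. They had not been summarised over the probes of a target sequence. The series-wide matrix held the same numbers, with a largest difference of 0. Each array carried 389307 probes, of which 383176 belonged to 42586 target sequences and 6131 were random-sequence controls, and 42566 of the targets had 9 probes. Joint normalization forces 1 intensity distribution on all arrays, so a change in total mRNA per cell is not measured, and every difference is relative to the other genes on the array.

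Probe intensities were log2 transformed, quantile normalized once more, which changed no value by more than 0.0143, and summarised to 1 value per target sequence (a probe set) by median polish. Probe sets were named through the Entrez gene link of the array annotation and a mouse RefSeq gene table. A symbol was found for 38654 probe sets, which stood for 21700 genes, and 3932 stayed unnamed. Where a gene had several probe sets, the 1 with the highest mean over all 18 arrays was used for gene values and lists. The array annotation names no genome build, so no positions are given.

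For each probe set limma 3.58.1 in R 4.3.3 fitted the 6 group means to all 18 arrays, with 1 estimate of the spread shared by the groups, and its moderated test (eBayes, two-sided) gave a p per contrast. Values were adjusted by Benjamini-Hochberg over the 42586 probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. Counts at an unadjusted p under 0.05 are given beside some results. Each count given is a share under 0.05 of the 42586, fewer than unchanged probe sets in independent arrays would give on average. These counts are therefore no sign of further signal, and the fit, which leaves out any pairing of arrays, may miss differences. The contrasts were KO against WT in each of the 3 conditions and averaged over them, the TGF-beta effect in each genotype, averaged and by genotype, and the TCR stimulation effect in each genotype, averaged and by genotype, 12 in all. Errors are standard errors (SE) from this fit unless given as a standard deviation (SD) or, for the size of a response, as described below, and each group mean rests on n = 3 arrays. The background of a group is the mean of its arrays' 95th percentiles of random probes. Where 1 of 2 groups lay below it, the difference measured from the background is given as a lower bound, and where both did, no size is given. Over more than 2 groups, fitted differences of such genes are no bounds, and the groups below are named. For the size of the TGF-beta response the mean was also taken with such group means set at the background. These limits were added after seeing the data. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the data.table package (1.17.8).

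Genes to be named were chosen by a rule fixed before the data were examined. It took Smad3, then per contrast the 8 largest rises and 8 largest falls among called genes whose 2 groups did not overlap (no overlap rule for averaged contrasts). Clone names and antigen receptor segments were passed over. Where under 5 named genes were called, the 5 with the smallest p are given as values. From each of 22 gene lists, up to 4 called members, or otherwise 2 members with the smallest p, were added. The values of 1 gene that the rule named are not reported here.

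The lists, also fixed beforehand, were TGF-beta target and feedback genes; TGF-beta ligands, receptors and Smads; regulatory T cell, Th17, Th1 and Th2 genes; T cell activation, naive T cell and quiescence, and T cell receptor signalling genes; G1/S and G2/M cell cycle, ribosome biogenesis, glycolysis, amino acid transport and one-carbon, and sterol and fatty acid synthesis genes; interferon response and apoptosis genes; and markers of memory T cells, B cells, CD8 T and NK cells, myeloid cells, and erythroid cells and platelets. The regulatory T cell gene Tigit was not on the array. Each list was tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 22 lists of a contrast, and again with a correlation estimated from the arrays. In 0 of the called lists did the median, mean and test differ in sign; among lists not called they differed in places, as for T cell receptor signalling genes in stimulated WT cells (median -0.01, mean 0.03, test downward). Counts of list members are given over all probe sets and adjusted over the list alone.

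To compare the size of a response between genotypes, genes were chosen by the effect averaged over genotypes. In this balanced design it is independent of the difference between them if the arrays are independent and equal in spread. The pairing described below, found in WT but not for the KO TGF-beta group, departs from this, so the choice of genes may not be neutral. The difference was tested with limma's fry, adjusted over the 2 responses tested, and with an exact permutation of genotype labels within each condition. The permutation takes the genotypes to be alike in both conditions, so it does not test equal responses alone.

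No depth applies to arrays; their number limits the precision. Between 42.8% and 59.6% of an array's target probes lay above the 95th percentile of its random probes. When known changes were added to the arrays of the medium comparison, limma called 9 of 50 probe sets changed by 1 on the log2 scale, 40 of 50 changed by 2 and 49 of 50 changed by 3. In simulated unchanged arrays, with errors drawn independently for each array, it made at most 1 false call in any contrast. With known changes added to such simulated arrays it made 8 false calls in the medium comparison. The real arrays are not independent in this way, so the simulation does not measure false calls in them.

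Replicate numbers in the labels were checked for pairing by the correlation of deviations from the group means between arrays with the same number. Every such correlation was over 0.1 between WT and KO in medium (lowest 0.689), WT in medium and with TGF-beta (0.577), WT with TGF-beta and with TCR stimulation (0.278), and WT and KO with TCR stimulation (0.175). These comparisons were taken as paired by number, from the values alone, as the labels do not say what a number marks. Comparisons with the KO TGF-beta group were not, since its numbers gave correlations down to -0.252.

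Alternatives fixed before the data were examined were the values as deposited, the series-wide matrix, cyclic loess, the mean of probes in place of median polish, the brighter part of the probe sets, an intensity trend with robust variance, a fit to the contrast's own groups alone, the replicate number as a block, the slide as a random block, array weights, leaving out each array in turn, and leaving out both medium replicates numbered 1. Other alternatives were added after seeing the data. They were the image number (read from the image name) as a block and the 3' to 5' probe ratio and random background as covariates. Others were the gene lists without each array in turn and without the 6 arrays numbered 2, and leaving out a doubted pair of arrays. For the array weights limma's gene-by-gene method was used, because its default did not converge. No deposited array was left out of the reported values.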

Results

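The series asked which genes TGF-beta changes in naive CD4 T cells through Smad3, an intracellular mediator of TGF-beta signals. It measured 18 arrays in 6 groups of 3 replicates, for 2 genotypes in 3 culture conditions. The 95th percentile of the random probes, taken as the background, lay between 7.61 and 8.55 on the log2 scale in 17 arrays and at 9.08 in KO with TGF-beta replicate 2. In the first principal component, which held 38.6% of the variance, 5 arrays stood apart. The 5 arrays were replicate 2 of every group but KO with TGF-beta, whose replicate 2 has the number 3 in its image name. Their lowest value was 56.3, against a highest value of 11.6 in the other 13 arrays.

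**Figure D1:**
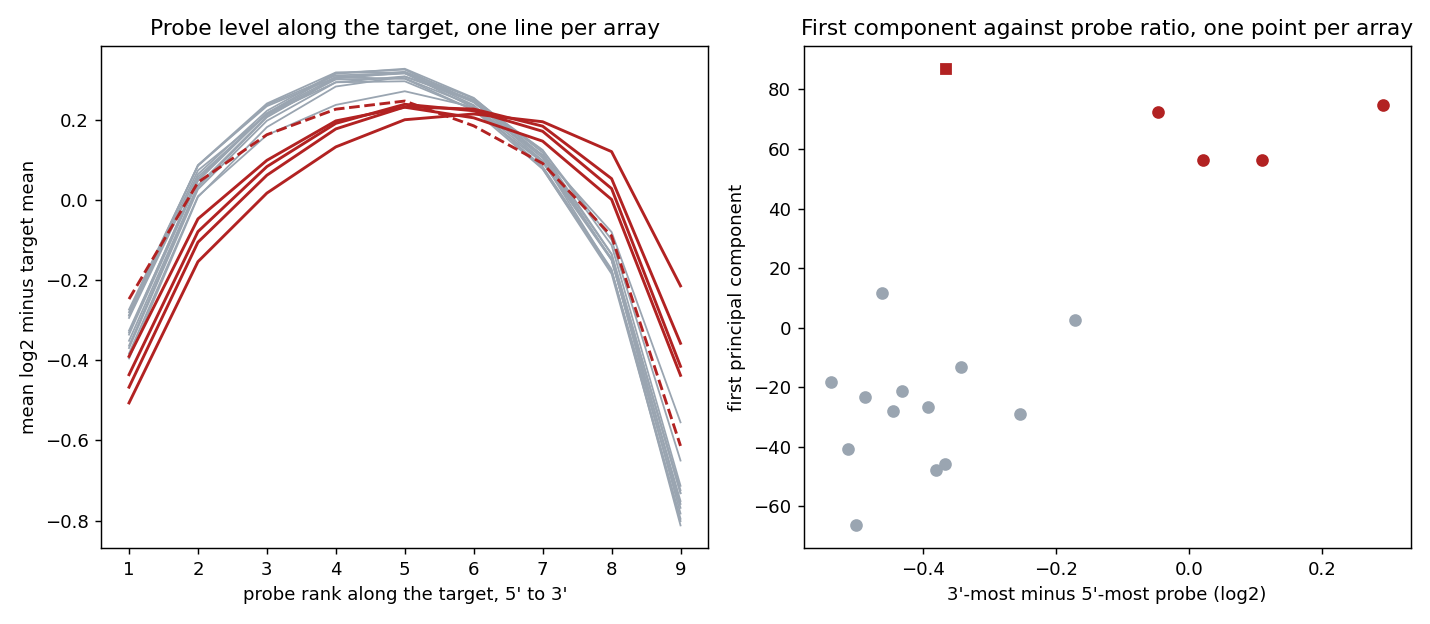
Left, mean log2 probe level by rank from the 5' to the 3' end of the target for each array, relative to the target's mean; right, first principal component against the 3'-most minus 5'-most probe level (log2). The 5 arrays that stand apart are red, with WT TCR replicate 2 dashed or square.

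Smad3 itself gave similar signals in both genotypes. Its mean log2 intensity was 12.79 ± 0.10 (SD, n = 3) in WT and 12.67 ± 0.24 (SD, n = 3) in KO cells in medium. The KO minus WT difference was -0.12 ± 0.18 in medium, -0.18 ± 0.18 with TGF-beta and -0.17 ± 0.18 with TCR stimulation, and none was called, with adjusted p = 1, 0.925 and 0.9999. The 9 probes of Smad3 start between positions 3951 and 4464 of its target sequence. The labels do not state which part of the gene is deleted, so these probes do not check the genotype.

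The response of WT cells to 6 h of TGF-beta was a set of rises. Ctsw, which encodes the lymphocyte cysteine protease cathepsin W, rose 11.4-fold, by 3.52 ± 0.28 on the log2 scale, from 10.44 ± 0.30 to 13.96 ± 0.40 (SD, n = 3; adjusted p = 4.17e-05). Kcnip2, a potassium channel-interacting protein, rose by 3.82 ± 0.63 and Apol9a, an apolipoprotein L family member, by 3.03 ± 0.32 (adjusted p = 0.0333 and 0.00117). Skil, which encodes the Smad corepressor SnoN, rose by 2.38 ± 0.31 (adjusted p = 0.00919). Pstpip2, an F-BAR protein of the cytoskeleton, rose by 1.99 ± 0.33 and Art4, an ADP-ribosyltransferase family member, by 1.90 ± 0.25. Mmp11, a matrix metalloproteinase also called stromelysin-3, and Spsb1, a SOCS-box protein, rose from medium levels below the background, by at least 1.77 and 1.66 when measured from the background. Limma called 23 probe sets, standing for 14 genes, as risen and 0 as fallen, while 841 of all 42586 had an unadjusted p under 0.05.

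Of the 22 TGF-beta target and feedback genes, all measured, 1 rose over all probe sets (Skil) and 21 did not pass. Adjusted over the list alone 5 rose, the others being Klf10 at 1.15 ± 0.30, Ski at 0.73 ± 0.25, and Ccr8 and Pmepa1, whose medium levels lay below the background, at 1.28 and 1.41 or more when measured from it. The list rose as a group, with a median of 0.32 and adjusted p = 2.07e-09, or adjusted p = 0.000264 with an estimated correlation. The lists of TGF-beta ligands, receptors and Smads (median 0.20, adjusted p = 0.00046), T cell activation genes (0.24, adjusted p = 0.00046) and regulatory T cell genes (0.24, adjusted p = 0.00548) were also called upward, with 0 members called in each, over all probe sets or adjusted over the list alone. With an estimated correlation these calls were lost, with adjusted p = 0.0676, 0.414 and 0.414. The last 2 depended on replicate 2, whose arrays stand apart, and were lost without the 6 arrays numbered 2 (adjusted p = 0.431 and 0.316). The activation list had means of 10.55 in medium and 11.04 with TGF-beta in replicate 2, but of 10.82 and 10.84 in replicate 1 and 10.87 and 10.96 in replicate 3. Its call was lost without WT medium or WT TGF-beta replicate 2 (adjusted p = 0.207 and 0.0747), and that of the regulatory list without WT medium replicate 2 or WT TGF-beta replicate 3 (adjusted p = 0.834 and 0.116). In replicate 2 the mean of B cell markers also went from 8.45 to 9.04 and that of myeloid cell markers from 7.85 to 8.41. In replicates 1 and 3 B cell markers did not rise (9.31 to 9.07 and 10.17 to 10.10), and myeloid cell markers rose less (8.44 to 8.45 and 8.87 to 8.96). Foxp3, the lineage factor of regulatory T cells, differed by -0.31 ± 0.48 (adjusted p = 1). In the Th17 list Maf, 0.17 above the background in its TGF-beta group and below it in medium, passed when adjusted over the list alone (adjusted p = 0.0179) and not over all probe sets (adjusted p = 0.826). With the replicate number as a block, where the pairing holds, glycolysis genes and amino acid transport and one-carbon genes were called downward and myeloid cell markers upward (adjusted p = 0.0285, 0.0447 and 0.0447, against adjusted p = 0.059, 0.0675 and 0.314 without the block). The count of 23 fell to 4, 7 and 6 without WT medium replicates 1, 2 and 3, and to 8, 13 and 5 without WT TGF-beta replicates 1, 2 and 3. A limma fit to the 6 arrays of the groups alone called 0, with 773 at an unadjusted p under 0.05; Ctsw and Apol9a stayed called without any 1 of the 18 arrays.

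In KO cells no probe set passed the test for TGF-beta against medium. The genes with the smallest p had log2 differences of at least 1.79 (Apol9a, measured from the background, under which its medium level lay), 1.501 ± 0.25 (Art4), 3.54 ± 0.63 (Kcnip2), 1.42 ± 0.28 (Bpgm, which encodes bisphosphoglycerate mutase) and 1.54 ± 0.31 (Skil), with adjusted p = 0.191, 0.199, 0.282, 0.61 and 0.658. Ctsw stood at 9.47 ± 0.46 in medium and 10.17 ± 0.43 with TGF-beta (SD, n = 3). Limma called 0 probe sets while 1341 had an unadjusted p under 0.05, and the smallest adjusted p of any was 0.104. All 23 probe sets called in WT had a positive difference in KO.

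The 22 TGF-beta target and feedback genes rose as a list in KO as well, with a median of 0.33, adjusted p = 0.000771, or adjusted p = 0.0146 with an estimated correlation. Members called numbered 0 over all probe sets and 1, Skil, adjusted over the list alone. The 25 ribosome biogenesis genes fell as a list by a median of -0.22 (adjusted p = 0.026), with 0 members called either over all probe sets or adjusted over the list alone. That call was lost with an estimated correlation (adjusted p = 0.657), without KO TGF-beta replicate 2, the array of highest background (adjusted p = 0.434), and without KO medium replicate 2 or 3 (adjusted p = 0.0597 and 0.0913). The mean of the ribosome biogenesis genes was 11.90 in that array and 12.28 and 12.32 in the other two. Without it regulatory T cell genes (adjusted p = 0.0399) and G2/M cell cycle genes (adjusted p = 0.00433) were called upward, against a medium group whose replicate 2 was low (G2/M mean 7.97, against 8.59 and 8.42); without the 6 arrays numbered 2 neither was called. Without WT TGF-beta replicate 2, 1 probe set was called.

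Averaged over both genotypes, TGF-beta raised 27 probe sets and lowered 1, standing for 16 and 1 named genes. The rises included Kcnip2 (3.68 ± 0.45), Apol9a (2.52 ± 0.22, from a KO medium level below the background), Ctsw (2.11 ± 0.20), Skil (1.96 ± 0.22), Art4 (1.70 ± 0.18), Bpgm (1.57 ± 0.20), Tubb3, a beta-tubulin (1.45 ± 0.22), and Spsb1 (1.54 ± 0.19, from medium levels below the background), with adjusted p from 0.000222 to 0.0143. Gpr183, the oxysterol receptor EBI2 that guides lymphocyte migration, fell by 0.99 ± 0.14 (adjusted p = 0.00793). Among the TGF-beta target and feedback genes 1 rose over all probe sets and 6 when adjusted over the list alone, and the list was called with adjusted p = 5.87e-10, or adjusted p = 0.000199 with an estimated correlation. Regulatory T cell genes were called upward (adjusted p = 0.016), with Nrp1 (0.60 ± 0.18) and Entpd1, which lay below the background in all 4 groups, passing when adjusted over the list alone and 0 over all probe sets. Glycolysis genes (median -0.15, adjusted p = 0.0116) and amino acid transport and one-carbon genes (median -0.17, adjusted p = 0.0103) were called downward, with 0 members called over all probe sets or adjusted over the list alone. With an estimated correlation these 3 calls were lost, with adjusted p = 0.554, 0.375 and 0.419, as they were without the 6 arrays numbered 2 (adjusted p = 0.348, 0.211 and 0.201). The regulatory list rose mostly in replicate 2, from 8.95 to 9.39 in WT and from 9.03 to 9.24 in KO, against 9.49 and 9.502 in WT replicate 1, 9.69 and 9.75 in KO replicate 1, 9.49 and 9.70 in WT replicate 3 and 9.56 and 9.55 in KO replicate 3. The KO arrays share only a number here and are not taken as pairs. Its call was lost without WT or KO medium replicate 2, WT TGF-beta replicate 2 or 3, or KO TGF-beta replicate 1 (adjusted p = 0.165, 0.151, 0.0722, 0.053 and 0.122), and that of glycolysis without WT medium replicate 2 (adjusted p = 0.0714). The amino acid list was not called without WT medium replicate 1, WT TGF-beta replicate 2 or KO TGF-beta replicate 2 (adjusted p = 0.0842, 0.0615 and 0.0708). Without the last, but not without the 6 arrays numbered 2, T cell activation genes, TGF-beta ligands, receptors and Smads, and G2/M genes were called upward (adjusted p = 0.00311, 0.0134 and 0.02). The count of 28 fell to 15 without WT medium replicate 1, KO medium replicate 1 or KO TGF-beta replicate 3, to 17 without WT TGF-beta replicate 3 or KO TGF-beta replicate 1, and to 18 without WT TGF-beta replicate 2.

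**Figure D2:**
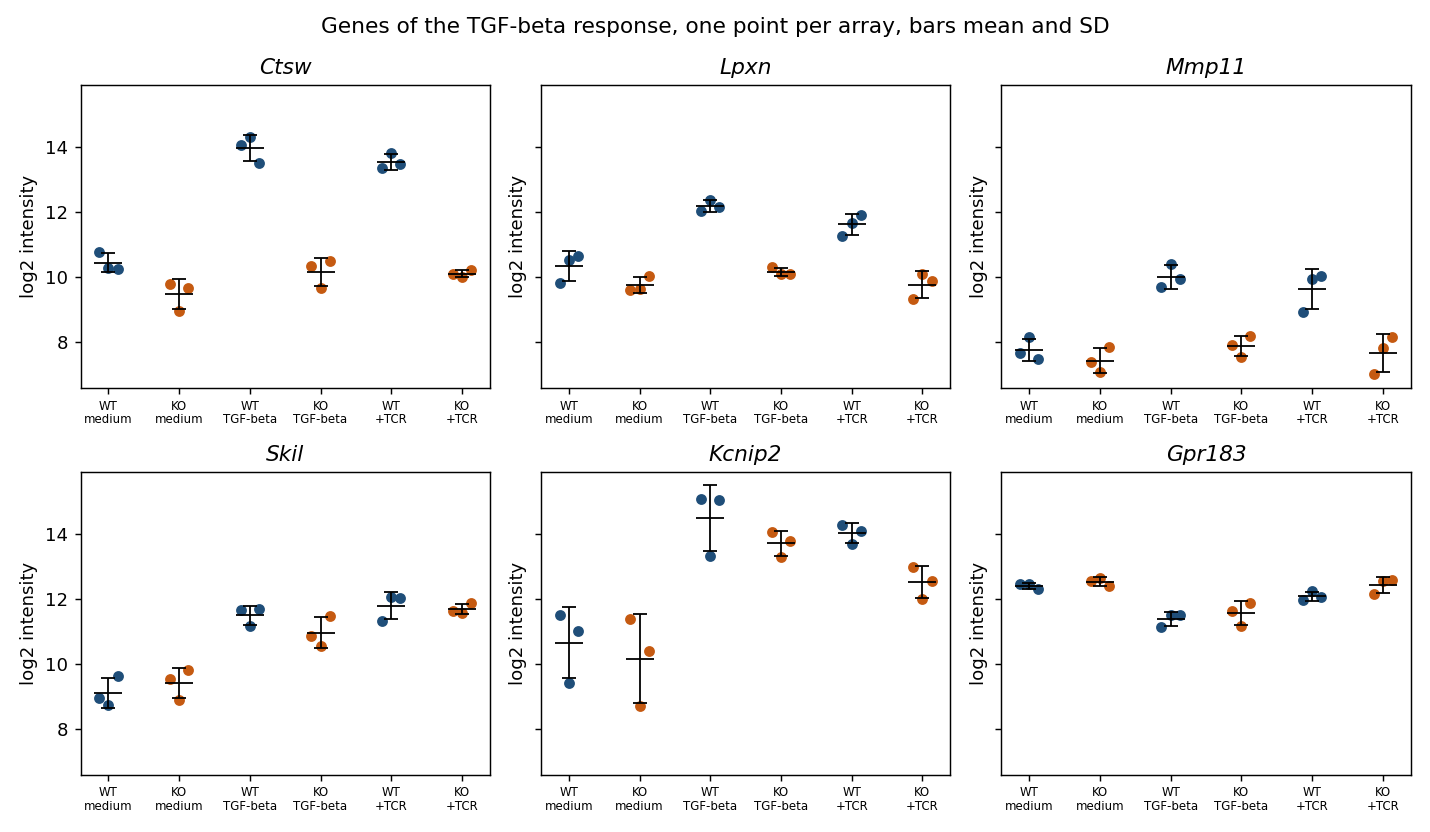
Log2 intensity of 6 genes in each array by genotype and culture condition, with the group mean and SD (n = 3); +TCR stands for TGF-beta with TCR stimulation. Ctsw averaged 13.96 in WT and 10.17 in KO with TGF-beta, while Skil averaged 11.50 and 10.96.

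Whether the TGF-beta response depended on Smad3 was tested on the 14 genes whose brightest probe set was called for the averaged effect. All 14 changed less in KO than in WT, 13 of them rises and 1 a fall. The median change in their own direction was 1.89 in WT and 1.15 in KO, and the mean change in KO was 60.6% of that in WT, a difference of -0.83 ± 0.21 on the log2 scale. Ctsw changed by 3.52 in WT and 0.70 in KO, and Lpxn, which encodes the adhesion adaptor leupaxin, by 1.85 and 0.39. At the other end Kcnip2 changed by 3.82 and 3.54, Fmnl3 by 1.28 and 1.19, and Gpr183 by -1.02 and -0.97. Of the 14, 3 had a medium level below the background, Spsb1 and 1110032F04Rik in both genotypes and Apol9a in KO. With those levels set at the background all 14 still changed less in KO, with medians of 1.81 and 1.05 and a mean difference of -0.84.

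The difference in size was called by fry (adjusted p = 0.000854). The exact permutation of genotype labels gave p = 0.1 over 400 arrangements. Among the arrays with TGF-beta the 14 genes had a mean KO minus WT difference of -1.10 in their own direction, and in medium of -0.27, each with an exact two-sided p = 0.1, the smallest that 3 arrays against 3 allow. Gene by gene, limma called 0 probe sets for the difference of the TGF-beta effect by genotype, and 787 had an unadjusted p under 0.05. The smallest was Ctsw at -2.82 ± 0.39 (adjusted p = 0.0918), followed by Lpxn at -1.46 ± 0.36, Pou6f1 at -1.39 ± 0.37, and Mmp11 and Acvr1, which lay below the background in 3 and 2 of the 4 groups, all 4 with adjusted p = 0.993. No list was called for this difference, the smallest adjusted p being 0.0517 for T cell activation genes. With the mean of a gene's probe sets 3 lists were called downward, namely ribosome biogenesis, TGF-beta ligands, receptors and Smads, and T cell activation (adjusted p = 0.0258, 0.0375 and 0.0411). The last was also called downward without 9 of the 18 arrays, each left out alone, with a smallest adjusted p = 0.00111 without KO TGF-beta replicate 1. Without KO medium replicate 2, 1 probe set was called.

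**Figure D3:**
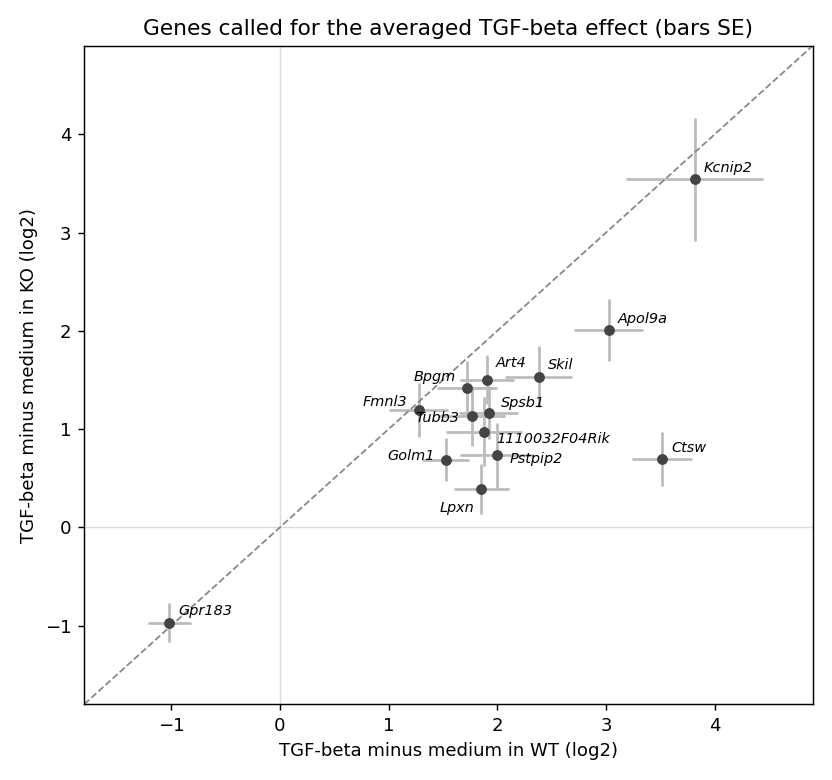
Change of each of 14 genes on TGF-beta in WT (horizontal axis, log2) and in KO (vertical axis, log2), with SE bars; the dashed line marks equal change. The 13 rising genes lie below the line, Ctsw at 3.52 and 0.70.

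In medium alone the genotypes were not told apart in any gene. The smallest p values belonged to Ctsw at -0.97 ± 0.28 (KO minus WT) and to Dnajc5b, Olfr8, Tnmd and Gfral, which lay below the background in both genotypes (adjusted p = 1 for each). Limma called 0 probe sets and 336 had an unadjusted p under 0.05, fewer than unchanged probe sets in independent arrays would give. No list was called, and the smallest adjusted p was 0.444. Without KO medium replicate 2 or WT medium replicate 3, however, B cell markers (adjusted p = 0.00614 and 4.21e-06) and myeloid cell markers (adjusted p = 0.027 and 0.038) were called higher in KO, and without the former regulatory T cell genes too (adjusted p = 0.0189). Leaving out 1 of these arrays breaks a pair of the same number. In replicates 1 to 3 the B cell marker means were 9.31, 8.45 and 10.17 in WT and 9.56, 8.83 and 10.14 in KO. They differed more between replicates than between genotypes, so these calls are not separate from that imbalance. Among the markers of other cell types, B cell markers had a median difference of 0.17 (adjusted p = 0.444).

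With TGF-beta, 4 probe sets were lower in KO than in WT. Ctsw was 13.8-fold lower, with a difference of -3.79 ± 0.28 (adjusted p = 1.4e-05). Lpxn differed by -2.03 ± 0.25 (adjusted p = 0.0135) and Nrarp, a Notch-induced regulator of Notch signalling, by -1.91 ± 0.28 (adjusted p = 0.0382). The fourth call was a probe set of Mmp11, whose brighter probe set had a mean of 10.01 in WT and 7.89 in KO (adjusted p = 0.117). The KO mean lay below the background of 8.22, so the difference was at least 1.79 in size. Pou6f1, a POU-domain transcription factor, differed by -1.57 ± 0.26 (adjusted p = 0.135). Ccr8 and Pmepa1 of the TGF-beta target list stood at -1.13 ± 0.32 and -1.10 ± 0.51, and that list as a whole was not called (median -0.13, adjusted p = 0.263). No other list was called either, with a smallest adjusted p of 0.0557, but T cell activation genes were called lower in KO without KO TGF-beta replicate 1 (adjusted p = 0.00114). That removal gives more weight to KO TGF-beta replicate 2, the array of highest background, whose activation mean was 10.37 against 10.81 in replicate 3. Without replicate 2 the list was not called.

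Ctsw stayed called without any 1 of the 18 arrays. The count of 4 became 2 without any 1 of the 6 medium arrays, WT TCR replicate 3 or KO TCR replicate 3, and 1 without WT TGF-beta replicate 2 or 3 or any 1 of the KO TGF-beta arrays. Limma on the 6 arrays of the groups alone called 0, with 402 at an unadjusted p under 0.05.

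With TGF-beta and TCR stimulation the same 2 genes led. Ctsw was 10.8-fold lower in KO, at -3.43 ± 0.28 (13.54 ± 0.25 in WT and 10.11 ± 0.12 in KO, SD, n = 3; adjusted p = 5.91e-05). Lpxn differed by -1.85 ± 0.25 (adjusted p = 0.0409), and the last of the 3 called probe sets was the dimmer one of Mmp11, whose brighter one lay below the background in KO, with a difference of at least 1.62 (adjusted p = 0.354). Stx1a, which encodes syntaxin-1A, differed by -1.497 ± 0.29 and Apol9a by -1.62 ± 0.32 (adjusted p = 0.594 and 0.631). Of the TGF-beta target list 1 member, Ccr8 at -1.51 ± 0.32, passed when adjusted over the list alone and 0 over all probe sets. In their own direction on TGF-beta, the 14 genes of the TGF-beta response averaged -1.01 in KO against WT, with an exact p = 0.1, the smallest possible. In that direction 14 of 14 lay lower in KO, where Gpr183, which fell on TGF-beta, counts with its sign turned.

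Ribosome biogenesis genes were called higher in KO as a list after TCR stimulation (median 0.08, adjusted p = 0.00255), with 0 of 25 members called over all probe sets or adjusted over the list alone. This was lost with an estimated correlation (adjusted p = 0.492) and without WT TCR replicate 1 or 3 or KO TCR replicate 3 (adjusted p = 0.0662, 0.167 and 0.216). With the mean of a gene's probe sets T cell activation, glycolysis, amino acid transport and one-carbon, and sterol and fatty acid synthesis genes were called higher in KO too, and Th17 genes lower (adjusted p = 0.0359 each). Further lists were called without single arrays. Without KO TCR replicate 1 they included sterol genes, higher in KO (adjusted p = 1.07e-07), and Th17 genes, lower (adjusted p = 0.00349). Replicate 1 had a low sterol mean in both genotypes (11.18 in WT, 11.19 in KO), so that removal breaks a pair. Without the 6 arrays numbered 2 interferon response genes and memory T cell markers were called lower in KO (adjusted p = 0.00916 and 0.0356). So were TGF-beta ligands, receptors and Smads (adjusted p = 0.0356). Amino acid transport and one-carbon genes and T cell activation genes were then called higher in KO (adjusted p = 0.00137 and 0.00916). The ribosome biogenesis call was kept in that setting (adjusted p = 1.08e-05). The count of 3 became 1 without any 1 of 15 arrays, the exceptions being WT medium replicate 1 and WT TCR replicates 1 and 2, and 1 in limma on the arrays of the groups alone. Ctsw remained called in each.

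Averaged over the 3 conditions, 9 probe sets were lower and 0 higher in KO, for 6 named genes and 1 unnamed target. Ctsw differed by -2.73 ± 0.16 (adjusted p = 5.17e-07), Lpxn by -1.48 ± 0.15 (adjusted p = 0.000586), Apol9a by -1.26 ± 0.18, Nrarp by -1.11 ± 0.16 and Stx1a by -1.09 ± 0.16. Mmp11 was lower too, with no size given because it lay below the background in 4 of the 6 groups; the last 4 genes had adjusted p from 0.0129 to 0.0307. Apol9a and Nrarp lay below it in 1 group each. Of the TGF-beta target and feedback genes 0 were called over all probe sets and 1, Ccr8 at -0.81 ± 0.19 with 1 of 6 groups below the background, adjusted over the list alone. Among regulatory T cell genes Nrp1, at -0.52 ± 0.14, passed when adjusted over the list alone. No list was called as a group, with a smallest adjusted p of 0.489. B cell markers were called higher in KO without 1 of 5 arrays, with adjusted p down to 0.000332 without WT medium replicate 3, a removal that breaks a pair as in medium. Ribosome biogenesis genes were called higher in KO without the 6 arrays numbered 2 (adjusted p = 0.000427), and Th17 genes lower without KO TCR replicate 1 (adjusted p = 0.0352). The count of 9 became 5 without KO medium replicate 3, WT TCR replicate 3, KO TCR replicate 1 or KO TCR replicate 3. Ctsw, Lpxn and Mmp11 stayed called without any 1 array.

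TCR stimulation of WT cells, in the presence of TGF-beta, changed many genes, and the lists of T cell activation and of amino acid transport and one-carbon genes rose. Bcat1, the cytosolic branched-chain aminotransferase, rose 12.6-fold (3.66 ± 0.23) and Pdcd1, the inhibitory receptor PD-1, 11.3-fold (3.503 ± 0.51). Lad1 (3.57 ± 0.40), the chemokine receptor Ccr8 (3.44 ± 0.32) and the signalling inhibitor Spry1 (3.18 ± 0.49) rose as well. Pdgfb, a growth factor chain, Sult2b1 and Il2, the T cell growth factor, rose from below the background, by at least 3.91, 2.96 and 2.43 when measured from it. Falls were led by Cdc25b, a cell cycle phosphatase, at -2.31 ± 0.29, Ampd3, an AMP deaminase, at -2.12 ± 0.45, Rapgef4, a cAMP-activated exchange factor, at -2.11 ± 0.26, Mgst2 (-1.96 ± 0.41), Fry (-1.95 ± 0.38), Cerkl (-1.88 ± 0.37), the integrin chain Itga4 (-1.87 ± 0.33) and Mettl27 (-1.81 ± 0.25). Adjusted p of these 16 genes ran from 1.04e-06 to 0.0261, with n = 3 arrays on each side. Limma called 384 probe sets as risen and 207 as fallen, for 266 and 155 named genes.

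Of 32 T cell activation genes 20 rose and 12 did not pass, and 26 rose adjusted over the list alone; they included Fosl2 (3.06 ± 0.42) and Nr4a2 (3.05 ± 0.51), with a list median of 1.59. Of 19 amino acid transport and one-carbon genes 14 rose and 5 did not pass, and 19 rose adjusted over the list alone, among them Pycr1 of proline synthesis (2.66 ± 0.41), Shmt1 (2.60 ± 0.33), Chac1 (2.46 ± 0.26) and Trib3 (2.27 ± 0.51). Of 25 ribosome biogenesis genes 8 rose and 17 did not pass, and 20 rose adjusted over the list alone, including Gnl3 (1.49 ± 0.35), Nop2 (1.28 ± 0.27), Nop58 (1.23 ± 0.22) and Utp20 (1.04 ± 0.24). The 3 lists were called with adjusted p = 1.17e-38, 4.3e-32 and 2.64e-19, or adjusted p = 0.000181, 0.000133 and 0.00079 with an estimated correlation.

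Smaller shifts were seen in 5 other lists, each lost with an estimated correlation. Among naive T cell and quiescence genes 3 of 22 fell, among them Pdcd4 (-1.24 ± 0.22) and the egress receptor S1pr1 (-1.01 ± 0.21), with 5 falls and 1 rise adjusted over the list alone; the list's adjusted p = 0.000573 became adjusted p = 0.251 with an estimated correlation. Of 25 interferon response genes 1 fell (Stat2, -0.78 ± 0.18) and 3 adjusted over the list alone (adjusted p = 0.000573, and adjusted p = 0.175 with an estimated correlation). Glycolysis genes rose with 2 of 18 called, Slc16a1 (1.39 ± 0.25), a lactate carrier, and Pgam1 (0.81 ± 0.18), and 4 adjusted over the list alone (adjusted p = 0.00228, and adjusted p = 0.104 with an estimated correlation). Of 15 regulatory T cell genes 3 rose, the interleukin-2 receptor chain Il2ra (2.92 ± 0.54), Tnfrsf4 (1.85 ± 0.35) and Gpr83 (1.48 ± 0.23), and 4 adjusted over the list alone (adjusted p = 0.00666, adjusted p = 0.317 with an estimated correlation, and adjusted p = 0.0595 without WT TCR replicate 3). Foxp3 differed by 0.68 ± 0.48 (adjusted p = 0.671). Among the TGF-beta target and feedback genes Ccr8 and the cell cycle inhibitor Cdkn1a (3.00 ± 0.48) rose, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.0132, and adjusted p = 0.0504 with an estimated correlation).

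The other 14 lists were not called in WT, with adjusted p from 0.124 (Th17) to 0.84 (G2/M cell cycle), though Th1 genes were with the mean of a gene's probe sets (adjusted p = 0.0479). T cell receptor signalling genes had a median of -0.01, sterol and fatty acid synthesis genes of -0.09 and Th2 genes of 0.07 (adjusted p = 0.621, 0.367 and 0.555). The markers of other cells had medians of 0.12 (B cells), 0.12 (myeloid cells), 0.10 (CD8 T and NK cells), 0.11 (erythroid cells and platelets) and 0.04 (memory T cells), with adjusted p = 0.718, 0.718, 0.828, 0.24 and 0.586. Among members of the 14 lists Tnf of the Th1 list (2.82 ± 0.35), Csf2 of the Th2 list (from below the background, by at least 1.13 above it), Ccnd2 of the G1/S list (1.21 ± 0.26), and Gadd45b (2.25 ± 0.44) and Bcl2l1 (1.87 ± 0.37) of the apoptosis list rose. With the replicate number as a block, where the pairing holds, limma called 1571 probe sets, 851 risen and 720 fallen, including all 591. The count became 220 without WT TGF-beta replicate 1, 345 without WT TGF-beta replicate 3, 331 without WT TCR replicate 2 and 9 in a fit to the 6 arrays of the groups alone.

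KO cells also changed widely on TCR stimulation. Nr4a3, an orphan nuclear receptor, rose 16.1-fold (4.01 ± 0.36) and Fosl2, an AP-1 subunit, 13.7-fold (3.78 ± 0.42). Spry1 (3.62 ± 0.49), the phosphatase Dusp2 (3.52 ± 0.58), Pdcd1 (3.48 ± 0.51) and Hivep3 (3.31 ± 0.33) rose too. The largest falls were of Rnf32 (-2.53 ± 0.58), Cdc25b (-2.47 ± 0.29), Rapgef4 (-2.37 ± 0.26), the kinase Map2k6 (-2.30 ± 0.48), the aquaporin Aqp3 (-2.16 ± 0.40), Elovl7 (-2.06 ± 0.43) and Cd7 (-2.05 ± 0.28). With Bcat1, Pdgfb and Dmbt1, the adjusted p of 16 genes ran from 3.06e-07 to 0.0251. Of these, Bcat1 and Pdgfb started below the background and rose by at least 3.86 and 3.39 when measured from it, and Dmbt1 fell to below it, by at least 1.18. Limma called 892 probe sets as risen and 434 as fallen, for 585 and 296 named genes.

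Activation genes rose in 22 of 32 members, with 10 not passing, and in 31 adjusted over the list alone, with a median of 2.01. Amino acid transport and one-carbon genes rose in 16 of 19 members and in 19 adjusted over the list alone, among them Shmt2 (2.77 ± 0.39) and Psat1 (2.47 ± 0.21). Ribosome biogenesis genes rose in 15 of 25 members and in 23 adjusted over the list alone, among them Gar1 (2.15 ± 0.52), Gnl3 (2.14 ± 0.35), Rrp9 (1.92 ± 0.38) and Rrs1 (1.91 ± 0.31). Their adjusted p = 2.14e-45, 1.1e-34 and 1.12e-27 became adjusted p = 8.07e-05, 8.07e-05 and 0.000138 with an estimated correlation. Glycolysis genes rose in 3 of 18 members, Slc16a1 (2.03 ± 0.25), Pgam1 (0.92 ± 0.18) and Hk2 (from below the background, by at least 0.23 above it), and in 7 adjusted over the list alone (adjusted p = 0.000103, and adjusted p = 0.0279 with an estimated correlation). Apoptosis genes rose in 3 of 15 members, Gadd45b (2.57 ± 0.44), Bcl2l1 (1.42 ± 0.36) and Fas (1.10 ± 0.26), and in 3 adjusted over the list alone (adjusted p = 0.000461, and adjusted p = 0.0232 with an estimated correlation); Bcl2l1 encodes a survival protein and Fas a death receptor. TGF-beta target and feedback genes rose in 4 of 22, Cdkn1a (3.16 ± 0.48), Ccr8 (3.06 ± 0.32), Rgs16 (2.40 ± 0.56) and Pmepa1 (2.30 ± 0.51), with 6 rises and 1 fall adjusted over the list alone (adjusted p = 0.00234, and adjusted p = 0.0164 with an estimated correlation).

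Interferon response genes fell in 3 of 25 members, Xaf1 (-2.02 ± 0.46), Stat2 (-0.86 ± 0.18) and Parp14 (-0.82 ± 0.21), and in 5 adjusted over the list alone (adjusted p = 8.82e-05, and adjusted p = 0.0898 with an estimated correlation). Regulatory T cell genes rose in 4 of 15, Il2ra (2.95 ± 0.54), Tnfrsf4 (2.41 ± 0.35), Tnfrsf18 (1.49 ± 0.36) and Gpr83 (1.48 ± 0.23), with 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.00707, and adjusted p = 0.335 with an estimated correlation). G1/S cell cycle genes rose in 2 of 25, Ccnd2 (1.01 ± 0.26) and Cdk6 (from below the background, by at least 0.77 above it), with 7 rises and 2 falls adjusted over the list alone (adjusted p = 0.0464, adjusted p = 0.363 with an estimated correlation and adjusted p = 0.0544 with the mean of a gene's probe sets). The G1/S call was lost without 1 of 8 arrays, with adjusted p from 0.0523 to 0.587. Without KO TGF-beta replicate 2 the last 2 lists had adjusted p = 0.0554 and 0.587. Naive T cell genes were not called as a list (adjusted p = 0.0813, but adjusted p = 0.0193 without that array, when G2/M genes were called downward too with adjusted p = 0.0393), although S1pr1 (-1.56 ± 0.21) fell and Ccr9, below the background in both groups, rose. The count of 1326 became 748 and 862 without KO TGF-beta replicates 1 and 2, and 858 and 495 without KO TCR replicates 1 and 3. A fit to the 6 arrays of the groups alone called 497.

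**Figure D4:**
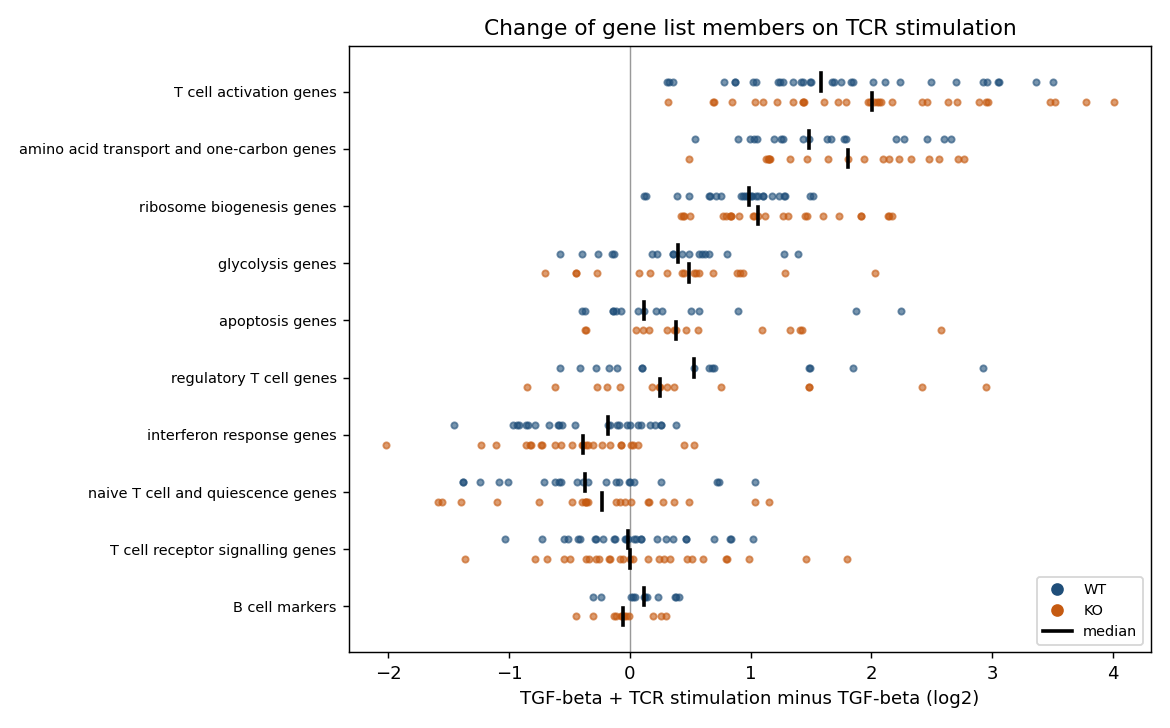
Log2 change of each measured member of 10 gene lists on TCR stimulation in WT and KO, 1 point per gene, with the list median as a bar. The activation list has medians of 1.59 in WT and 2.01 in KO, and the B cell marker list 0.12 and -0.05.

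The TCR response of the 2 genotypes overlapped in 353 risen probe sets, against 8.04 for independent lists, and in 165 fallen ones, against 2.11. No probe set was called in opposite directions, and the changes in WT and KO correlated across probe sets with r = 0.676, where probe sets are not independent replicates. For the difference by genotype limma called 0 probe sets, with 531 at an unadjusted p under 0.05. The smallest p values belonged to Acd at -1.005 ± 0.30 and to Olfr1277, Dok6, Mrc2 and Vmn1r235, which lay below the background in all 4 groups (adjusted p = 0.9996 for each). Among 1766 genes called for the averaged TCR effect, 1260 changed more in KO and 506 less, with medians of 0.856 in WT and 0.996 in KO. The mean difference in size, 0.16 ± 0.14, did not pass (fry adjusted p = 0.211, exact permutation p = 0.27 over 400 arrangements). By fry it passed without KO TCR replicate 2, at 0.22, where the permutation was not repeated.

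Of the lists, ribosome biogenesis genes (median difference 0.31), T cell activation genes (0.22), sterol and fatty acid synthesis genes (0.23), apoptosis genes (0.30) and amino acid transport and one-carbon genes (0.13) were called as more positive in KO for the difference by genotype. Their adjusted p = 0.000246, 0.000799, 0.00337, 0.0134 and 0.018 became adjusted p = 0.206, 0.337, 0.507, 0.206 and 0.362 with an estimated correlation. Members called numbered 0 in all 5 lists, over all probe sets and adjusted over the list alone. Without KO TGF-beta replicate 2, the array of highest background, of these 5 the ribosome biogenesis list alone was called (adjusted p = 0.0257, the others adjusted p = 0.14 to 0.192), and G2/M cell cycle and interferon response genes were called as more negative in KO (adjusted p = 0.0257 each, against adjusted p = 0.489 and 0.447 with all arrays). The amino acid list was also lost without WT TGF-beta replicate 3, WT TCR replicate 1 or 3, or KO TCR replicate 3 (adjusted p = 0.115, 0.057, 0.266 and 0.12), the sterol list without WT TCR replicate 1 or KO TCR replicate 3 (adjusted p = 0.321 and 0.12), and the apoptosis list without WT TGF-beta replicate 3 (adjusted p = 0.0754). Without the 6 arrays numbered 2 the sterol and apoptosis lists were not called (adjusted p = 0.683 and 0.447). Interferon response and G2/M cell cycle genes were then called as more negative in KO (adjusted p = 0.0003275 and 0.0222).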

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

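The tests of the first principal component, of the ribosome biogenesis genes and of the size of the TGF-beta response were chosen only after those results were seen, as were list tests without single arrays or those numbered 2 and the splits for the averaged TCR effect. The bounds of the ribosome biogenesis tests were changed, and the slide, image number and B cell tests replaced, after first values were seen. The counts over other splits for the other 11 contrasts were fixed before. The response to TGF-beta differed in size between the genotypes (fry adjusted p = 0.000854), and 5 gene lists differed in their change on TCR stimulation by genotype, namely ribosome biogenesis (adjusted p = 0.000246), T cell activation (adjusted p = 0.000799), sterol and fatty acid synthesis (adjusted p = 0.00337), apoptosis (adjusted p = 0.0134) and amino acid transport and one-carbon genes (adjusted p = 0.018). With an estimated correlation none of the 5 list differences passed, the smallest adjusted p being 0.206.

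The smaller TGF-beta response in KO was weighed against 3 technical explanations. Without KO TGF-beta replicate 2, the array of highest background, the mean KO minus WT difference was -0.70 ± 0.17 (SE), with the 3' to 5' probe ratio as a covariate it was -0.86 ± 0.19, and with the background of random probes as a covariate -0.72 ± 0.17, each on the same 14 genes and each more than 2 SE below 0. These values argue against each of the 3 as the whole cause. A candidate explanation is that part of the response needs Smad3, which stays a hypothesis, since other differences between the mice were not tested. The exact permutation p of 0.1 did not pass. It cannot decide the question, as it takes the genotypes to be alike in both conditions, while KO already lay lower in medium (-0.27).

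The image names carry a number whose meaning is not stated, and whether arrays that share it were handled together was not tested. The KO TGF-beta group holds no array with image number 2. Replicate 2 of 5 groups stood apart on the first principal component, and these are the 5 arrays with image number 2. In 4 of them a loss of signal from probes nearer the 5' end is a candidate explanation, as the lowest of their 3' to 5' log2 ratios lay 0.12 above the highest of the 13 other arrays, while in WT TCR replicate 2 the ratio of -0.37, below the mean of -0.26 of its group's other arrays, argues against it. The slide is argued against for the 3 arrays that share theirs, since the highest first component of their slide mates was -23.2, while it stays open for the 2 that are alone on theirs. B cells, which a complete sort for TCR beta and CD4 would remove, are argued against in the 3 arrays with TGF-beta. The marker means of these arrays lay within 0.149 of replicate 1 of their group, while replicates 1 and 3 there were at least 0.654 apart. B cells stay open in the 2 medium arrays, up to 0.858 below replicate 1, as do other cell types. No biological explanation was tested, as each of the 5 groups has 1 such array. The image names of WT and KO TCR replicates 2 mark them as repeats, and whether this bears on their place was not tested.

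Ribosome biogenesis genes had a median difference of 0.31 in their TCR change by genotype, positive in 21 of 25 genes. Without KO TGF-beta replicate 2 the median was 0.14, and that array may account for a large part of it. The list stayed called without it at the preset correlation (adjusted p = 0.0257). It also stayed called without every array numbered 2, that array among them (adjusted p = 0.00258). The call therefore did not rest on that array alone. After stimulation KO differed from WT by a median of 0.0797 and before it, with TGF-beta alone, by -0.18. A different start thus stays open as well, though it is not separate from KO TGF-beta replicate 2, without which the start was -0.0651. In replicates 1 and 3 the list means before stimulation were 12.28 and 12.32 in KO, against 12.18 and 12.36 in WT. KO thus started higher in replicate 1 and lower in replicate 3. After stimulation the means were 13.25 and 13.52 in KO, against 13.195 and 13.095 in WT. Without the 5 arrays of image number 2 the median was 0.321, which argues against the lack of an image number 2 array in the KO TGF-beta group. Smad3 deficiency remains open and was not tested apart from these.

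Other splits of the arrays were counted for each contrast. For KO against WT with TGF-beta (4 probe sets), with TCR stimulation (3), for TGF-beta in WT (23), and for TCR stimulation in WT (591) and KO (1326), 1 of 10 splits, the real one, gave as many, and the highest of the others gave 0. For KO against WT in medium and for TGF-beta in KO, where the real split gave 0 by limma (336 and 1341 at an unadjusted p under 0.05), all 10 of 10 gave as many, with a highest other of 0. Where the numbers pair the arrays, the other splits gave 0 whether they parted each pair or not. In these 7 contrasts the splits are too few for a share under 0.05. Averaged over conditions, KO against WT gave 9, with 1 of 100 splits as large and a highest other of 0, and the averaged TGF-beta effect gave 28, with 1 of 100 as large and a highest other of 4, from a split that kept the WT arrays and 4 of the 6 KO arrays on their real sides, so a random grouping is excluded at that share. The averaged TCR effect gave 3161, with 1 of 100 splits as large, which excludes a random grouping likewise, and a highest other of 2271, from a split with WT TGF-beta, WT TCR and KO TCR replicates 2, all of image number 2, on 1 side. The effects by genotype gave 0 by limma (787 and 531 at an unadjusted p under 0.05), so that 100 of 100 splits gave as many, with highest others of 2 for TGF-beta and 1164 for TCR stimulation. The split giving 2 amounts to the real KO against WT difference over medium and TGF-beta. The split giving 1164 counted WT and KO TCR replicates 2 and WT TGF-beta replicate 2, all with image number 2, with the same sign, and so points to a structure of the arrays; with the image number as a block, which takes KO TGF-beta replicate 3 out of the comparison as the 1 array of image number 4, limma called 0, with 1801 at an unadjusted p under 0.05.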

How the results depend on the processing

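The image number block, the 3' to 5' ratio and random background covariates, leaving out the doubted pair of arrays (KO TGF-beta replicate 2 and WT TCR replicate 2), and the gene lists without each array and without the 6 arrays numbered 2 were chosen after seeing the data. All 13 results kept their side or stayed within 1.5 times the count with the values as deposited, the series-wide matrix, the brighter part of the probe sets and the slide as a random block. The matrix holds the deposited values, so it repeats the same fit. The deposited values differ from those used by at most 0.0143, so the first 2 of these say little about robustness. No result was reversed by any alternative, and the size of the TGF-beta response stayed between -0.98 and -0.48. The counts of called probe sets that moved are given by limma as follows, and the cause was not tested. Array weights gave 14 (KO against WT with TGF-beta), 9 (the same with TCR stimulation), 25 (averaged over conditions), 41, 14, 93 and 1 (TGF-beta in WT, in KO, averaged and by genotype), and 1718 and 7768 (TCR stimulation in WT and KO). The arrays of the groups alone gave 0 (KO against WT with TGF-beta, 402 at an unadjusted p under 0.05), 1 (with TCR stimulation), 0 (TGF-beta in WT, 773 unadjusted), 9 and 497 (TCR stimulation in WT and KO). Cyclic loess gave 4 for TGF-beta in KO and 922 for TCR stimulation in WT, the mean of probes gave 4 for TGF-beta in KO, and an intensity trend with robust variance gave 1 for it and 1 for KO against WT with TCR stimulation. The image number block, in which KO TGF-beta replicate 3 as the 1 array of image number 4 no longer counts, gave 15 (KO against WT averaged), 4 (TGF-beta in KO), and 1864 and 2283 (TCR stimulation in WT and KO). The 3' to 5' covariate gave 5 (TGF-beta in KO), 44 (averaged) and 1141 (TCR stimulation in WT). Without both medium replicates numbered 1 the counts were 2 (KO against WT with TGF-beta), 4 (averaged), 6 (TGF-beta in WT) and 14 (TGF-beta averaged), and without the doubted pair 1 (KO against WT with TGF-beta) and 2 (TGF-beta in KO).

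With the replicate number as a block the counts were 1571 for TCR stimulation in WT, and, where the KO TGF-beta group is involved and its arrays share only a number, 10 for TGF-beta in KO, 50 averaged and 2958 for TCR stimulation in KO. There, 4 of the 6 KO medium and KO TGF-beta arrays and 1 of the 6 KO TGF-beta and KO TCR arrays correlated best with their own number. For contrasts averaged or by genotype the block added calls for 5 lists, in the TGF-beta effect averaged (adjusted p = 0.0488 for 3 lists) and by genotype (adjusted p = 0.0455 for 2 lists). Where the pairing holds it changed no other call than those given beside the results.

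Leaving out each array in turn gave ranges of 0 to 0 for KO against WT in medium, 1 to 6 with TGF-beta, 1 to 4 with TCR stimulation, 5 to 11 averaged, 4 to 26 for TGF-beta in WT, 0 to 1 in KO, 15 to 31 averaged, 0 to 1 by genotype, 220 to 777 for TCR stimulation in WT, 495 to 1631 in KO and 0 to 0 by genotype. The size of the TGF-beta response ranged from -0.98 to -0.61, and that of the TCR response from 0.046 to 0.24, passing without KO TCR replicate 2 at 0.22. Of 42 list calls over 12 contrasts 17 kept their call with an estimated correlation, 41 with the mean of a gene's probe sets (G1/S genes on TCR stimulation in KO were lost), 42 with the replicate block and 33 without KO TGF-beta replicate 2. Without any 1 array 27 of the 42 were kept and 15 were lost without at least 1, while 45 others were gained without at least 1; without the 6 arrays numbered 2, 33 were kept and 9 gained. The first 4 of these alternatives added 0, 13, 8 and 9 list calls; among the 13 are glycolysis for TGF-beta in WT, downward (adjusted p = 0.0219), and for TGF-beta averaged ribosome biogenesis and sterol and fatty acid synthesis downward and myeloid markers upward (adjusted p = 0.0318 each). Called named genes kept their call in 5510 of 6134 values and changed sign in 0, while those not called gained a call in 100 of 14794 and changed sign in 48. Of 192 pairs of a called gene and a contrast, 95 kept the call under every alternative. For KO against WT averaged over conditions, Ctsw kept its call in 32 of 32 alternatives, Apol9a in 20 and Stx1a in 14. Nrarp with TGF-beta and Lpxn with TCR stimulation kept theirs in 12 of 32 each. Signal over background limits the arrays most in KO TGF-beta replicate 2, where 42.8% of target probes lay above the random probes' 95th percentile.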

Other observations

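The genes given here were chosen after their values were seen. Averaged over both genotypes, TCR stimulation lowered 8 of 25 interferon response genes and raised 7 of 18 glycolysis genes. The interferon-induced genes Xaf1, Ifit3 and Zbp1 fell by 1.74 ± 0.32, 1.04 ± 0.24 and 1.04 ± 0.27 on the log2 scale. Ldha, Gapdh and the glucose transporter gene Slc2a1 rose by 0.56 ± 0.14, 0.64 ± 0.15 and 0.69 ± 0.17. Both lists were called (adjusted p = 5.2e-05 and 0.000225), and with an estimated correlation the first was lost (adjusted p = 0.0795) and the second kept (adjusted p = 0.0431). Among TGF-beta target and feedback genes 6 rose, including Junb at 1.58 ± 0.34, and 2 fell, Smurf1 at -0.84 ± 0.22 and Bambi at -0.46 ± 0.12.

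The mean of the 12 B cell markers differed between replicates more than between groups. It was 9.96 to 10.2 in replicate 3 of every group but KO with TGF-beta, where it was 9.64, and 8.45 to 9.56 in the other 12 arrays. A complete sort for TCR beta and CD4 would remove B cells. Its purity is not given, so B cells left in differing amounts are neither shown nor excluded. Myeloid cell markers ran from 7.85 to 8.96.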
